A study of Caenorhabditis elegans with 12 samples.

How the data were processed

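RNA was sequenced from whole Caenorhabditis elegans of 2 genotypes, wild type and a mutant of dlk-1, the kinase at the head of a p38 MAP kinase cascade. Animals of each genotype were kept for 9 h from the last larval stage with 0 or 1 mM fluvastatin, a statin, which is an inhibitor of HMG-CoA reductase. The 4 groups hold 3 libraries each. The sample titles name the mutant as lacking p38 and the protocols name dlk-1, and the allele is not given in the sources used here. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples only, which may be technical.

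Per the labels' protocols, libraries were made with a TruSeq RNA kit, which does not mark strand, and were read as 50 bp single reads on a single lane. Bowtie and DESeq2 are named in the submitters' processing notes, without versions or roles. The genome build and the annotation behind the values are not given in the sources used here. The deposited table gives a normalised signal, which is a read count divided by 1 size factor per library, for 34873 transcript models and noncoding loci in 12 columns. All 12 columns were used. Every deposited value was a whole multiple of its column's step (100% of values within 0.01 read), so whole reads could be recovered. The steps equalled the inverse of the median-of-ratios size factors of the same table, with a largest relative difference of 5.33e-10 over 20484 transcript models, and these factors lay between 0.843 and 1.18. Reads shared by isoforms were counted on each isoform, so sums over all transcript models are not sequencing depth.

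Transcript models were grouped into 30301 genes by sequence name. For the 3037 genes with several models, up to 17, the model with the highest mean over the 12 libraries was kept. With 1 model per gene the libraries held 9370975 to 12438131 reads, and 18562 to 19683 genes had reads. Ribosomal RNA took 0.395 to 1.11% of these reads, mitochondrially encoded genes 0.178 to 0.259%, and the 10 most abundant genes 2.33 to 3.54%. Counting error is small at this depth for abundant genes, and the spread between replicates sets the precision. No pair of replicates agreed within sampling noise, with a chi-square per degree of freedom of at least 9.16. Sequence names were matched to the WBcel235 annotation of Ensembl release 115 for 29775 genes, and coordinates and overlaps come from that annotation. 227 genes had values within 5% of another gene's in all libraries at a mean of at least 50 and are uncertain, since reads may be shared.

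Values were analysed as log2(value + 1). Genes with a value of at least 10 in at least 3 libraries were kept, which left 15529. Fold changes are on this scale and understate the change of low genes. All 4 groups were fitted together with limma 3.58.1 (trend and robust options, R 4.3.3), without a replicate term, and each comparison was tested two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values are from this fit unless another is named. The design fixed before the data were examined had planned edgeR's quasi-likelihood test for raw counts. The values are normalised, so limma took its place, and edgeR 4.0.16 on the recovered reads was added as an alternative.

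The comparisons were fluvastatin against control in each genotype, the difference between these effects, and mutant against wild type at each dose. A general response was a call in both genotypes with the same sign. A p38 dependent response was a wild-type call whose difference between genotypes was also called. The titles number the replicates 1 to 3 in every group. Deviations from the group means correlated between libraries of the same number in every pair (0.555 to 0.887). For different numbers the median was -0.523, which is no separate evidence, since centring groups of 3 makes it negative where same numbers correlate. All 12 libraries correlated best with a library of their own number. The numbers were therefore taken as pairing the samples, from these correlations and not from any label, and a fit with the replicate number as a block was planned as an alternative. Its value stands beside a result where it changes a call or moves a count by more than 1.5 times.

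Genes were named by a rule fixed before the data were examined. It takes 12 genes of the statin and p38 literature in every comparison, and up to 10 rises and 10 falls of largest size among called genes with non-overlapping groups and a mean of at least 5 CPM. For the difference it takes the 20 lowest p-values. It also takes up to 3 called members of each gene list, or where none passes the member with the lowest p. Genes named outside this rule are said to be so. The 32 gene lists were fixed at the same time, with 12 of 434 entries not found. Each was tested with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists, and members were counted with adjustment over all genes and adjusted over the list alone. Enrichment of 101 families of gene symbols was tested with Fisher's exact test, which was added after the data were seen.

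Alternatives changed the pseudocount (0.1 and 5), the low-value filter, the scaling, the threshold, the groups in the fit and the test (limma-voom, edgeR, DESeq2 1.42.0), or left out each library in turn. Summed transcript models, TMM scaling, leaving out all libraries of a replicate number, and an average of the genotype contrasts were added after the data were seen. The scripts were tested on simulated data with 50 genes changed per fold size among 15356. For fluvastatin in wild type, the fit without the block recovered 10% of genes changed 1.5-fold, 42% of those changed 2-fold and 84% of those changed 8-fold with 0 false calls. With the block the shares were 68%, 94% and 98%. False calls with the block numbered 10 for fluvastatin in wild type, 10 for the difference, 12 for the genotypes with fluvastatin, and 0 for the other comparisons. The changes were placed in the wild-type fluvastatin libraries only, so the comparisons with false calls were those that held changed genes. The adjustment allows false calls in proportion to true ones, and the comparisons with 0 held no changed genes. For the difference between genotypes, 6% of 2-fold and 56% of 4-fold changes were recovered without the block and 80% and 88% with it. All these shares belong to data with many changed genes and need not hold for a comparison with few calls.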

Results

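Whole-animal RNA was sequenced in 4 groups of 3 libraries: wild type and dlk-1 mutant, each with 0 or 1 mM fluvastatin for 9 h. The deposited libraries, counted with 1 transcript model per gene, held 9370975 to 12438131 reads, and 15529 genes were tested. In a principal component analysis of log2 values, the first component (58.5% of the variance) set replicate 2 of every group apart from replicates 1 and 3, and the second component (14.4%) parted fluvastatin from control. Cuticle collagens, moulting genes and sperm genes, which mark larval stage and germline, varied with the replicate number, with the median collagen at 0.86, -1.07 and 0.18 log2 units from its own overall mean in replicates 1, 2 and 3. The spread between replicates without a block therefore holds this difference, and results with the replicate number as a block are given beside those without it where they change a call.

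**Figure D1:**
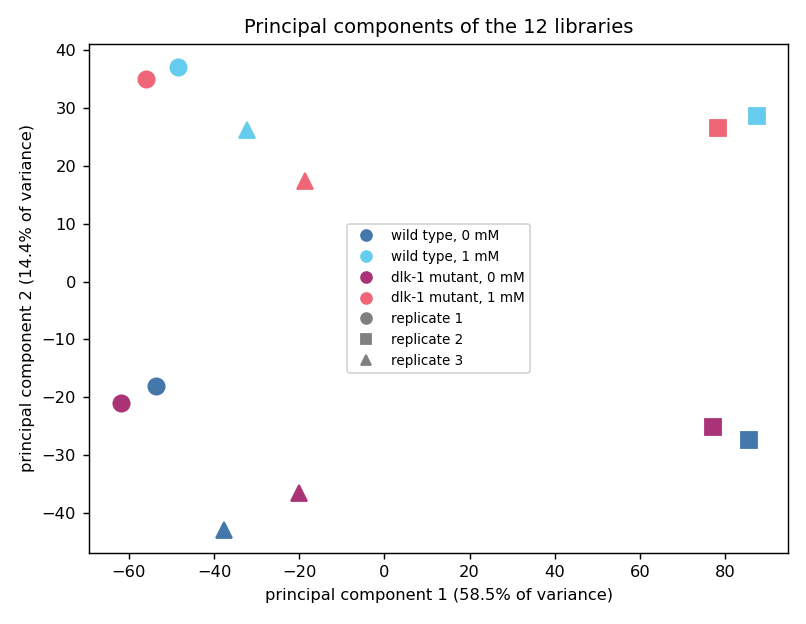
Principal components of log2(value + 1) for the 12 libraries, with colour for group and symbol for replicate number. The first component holds 58.5% of the variance and sets replicate 2 apart, and the second holds 14.4% and parts the treatments.

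dlk-1 itself (F33E2.2, chromosome I, 12565800 to 12572801 on the minus strand in WBcel235, overlapping mec-19, whose reads this kit cannot part by strand) was lower in the mutant but not absent. Without fluvastatin its normalised read counts were 961, 791 and 911 in wild type and 481, 541 and 506 in the mutant. With fluvastatin they were 1419, 983 and 1345 in wild type and 792, 706 and 804 in the mutant. The mutant level was lower in 6 of 6 pairs of the same replicate number, and the 5 transcript models stood at 43.6 to 72.5% of wild type. The log2 difference was -0.80 ± 0.14 (SE, n = 3 per group) without fluvastatin and -0.69 ± 0.14 with it, which did not pass over all genes (adjusted p = 1.0 for both) but did with the replicate block (adjusted p = 0.011 and 0.0218). dlk-1 was also higher with fluvastatin, by a log2 of 0.48 in wild type and 0.59 in the mutant, past the threshold with the block only (adjusted p = 0.00969 and 0.00255). What the mutation does to the protein cannot be read from these counts.

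The comparison of fluvastatin with control in wild type asks which genes respond to the statin. Genes of xenobiotic metabolism were among the largest rises. The cytochrome P450 cyp-35A3 went from 11.2 ± 1.62 to 1869 ± 350 normalised reads (SD, n = 3), a log2 change of 7.25 ± 0.40 (SE), and cyp-35A5 went from 37.7 ± 10.7 to 3185 ± 571 (log2 6.38 ± 0.25). The UDP-glucuronosyltransferase ugt-67 (H23N18.4) rose by a log2 of 6.62 ± 0.39 and the efflux pump pgp-1 by 2.79 ± 0.24. Genes of the infection response rose too: irg-6 (C32H11.1) from 11.1 ± 10.1 to 1559 ± 431 (log2 7.32 ± 0.63) and irg-4 (F08G5.6) from 252 ± 118 to 3044 ± 659 (log2 3.67 ± 0.40). The C-type lectin clec-206 (log2 8.46 ± 0.68), Y73C8C.10 (8.09 ± 0.55), H25K10.4 (7.35 ± 0.49) and the phospholipid-transporting ATPase gene tat-6 (6.55 ± 0.75) were also among the largest rises, all from control means under 6 normalised reads, where the pseudocount understates the fold.

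The largest falls in wild type were those of pud-3 (F15E11.15, log2 -5.73 ± 0.66) and pud-4 (F15E11.12, -5.71 ± 0.70), named for proteins with raised levels in insulin receptor mutants. pud-3 went from 741 ± 401 to 14.2 ± 9.18 normalised reads. pud-1.1 and pud-1.2, near-identical genes that may share reads, fell by 1.96 each. The thaumatin gene thn-2 (-2.85 ± 0.37), the UDP-glucuronosyltransferase ugt-53 (-3.44 ± 0.63), the lectins clec-166 (-2.67 ± 0.37) and clec-218 (-2.12 ± 0.31), E02H4.7 (-2.50 ± 0.28), F42A10.7 (-2.19 ± 0.43) and cth-1, which encodes a cystathionine gamma-lyase (-1.53 ± 0.28), fell as well. The tubulin gene tbb-6, known as a target of the PMK-3 p38 kinase, rose from 49.8 ± 26.6 to 414 ± 41.2 (log2 3.18 ± 0.48, adjusted p = 0.00547). hsp-4, the endoplasmic reticulum chaperone BiP, rose from 5423 ± 102.3 to 8069 ± 577 (log2 0.57 ± 0.09, adjusted p = 0.00856).

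The drug's own target did not move past the threshold in wild type: hmgr-1 (F08F8.2), which encodes HMG-CoA reductase, stood at 760.4 ± 153 in control and 802 ± 99.6 with fluvastatin (log2 0.09 ± 0.18), and hmgs-1 (F25B4.6), the synthase before it, at 318 ± 47.1 and 324 ± 28.5 (log2 0.03). The mitochondrial chaperone genes hsp-6 (0.03) and hsp-60 (-0.16), the desaturase genes fat-6 (0.02) and fat-7 (-0.54), and the kinase genes pmk-3 (0.02) and mkk-4 (0.23) did not pass in either fit. cebp-1 (D1005.3), a transcription factor downstream of DLK-1, passed only with the block (log2 0.55, adjusted p = 0.045).

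In wild type limma called 216 genes up and 66 down, of which 171 and 51 changed at least 2-fold. In all 282 the 3 treated libraries lay on 1 side of the 3 controls, which the call itself nearly requires and which chance gives for 10% of genes not chosen by a call. Of the 1091 calls with the block 780 did so. With the replicate block 586 rose and 505 fell, so that the share of rises went from 76.6% to 53.7%, and all 282 calls were kept; the blocked count of 1091 was 720 without wild-type fluvastatin replicate 3. The count fell from 282 to 56 without all libraries of replicate 1, 43 without those of replicate 3 and 257 without those of replicate 2. It was 167 without wild-type fluvastatin replicate 1, and 172 without wild-type fluvastatin replicate 3; it was 437 with DESeq2 and 166 with only the groups compared in the fit.

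Among the gene lists in wild type, 18 of 62 cytochrome P450 genes rose and 1 fell (22 and 6 adjusted over the list alone, 24 and 7 with the block). cyp-35A4 (log2 7.78) and cyp-35A1 (6.71) lead them with cyp-35A3, close paralogs that may share reads. The list as a whole was up (camera adjusted p = 2.83e-12, and 0.0252 with an estimated correlation). The fall, named after its value was seen, was that of cyp-34A8 (-0.75). Of 61 UDP-glucuronosyltransferase genes 23 rose and 2 fell (25 and 5 adjusted over the list alone, 27 and 6 with the block; camera adjusted p = 8.7e-21, and 0.12 with an estimated correlation), with ugt-10 (6.05) and ugt-33 (5.06) next to ugt-67, and ugt-30 (-2.37, named after its value was seen) next to ugt-53. Of 23 ABC transporter genes 3 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 8.12e-05, and 0.255 with an estimated correlation): pgp-1, pgp-3 (1.91) and pgp-11 (-1.17) were among them, and the block called 8 up and 2 down. Of 40 glutathione S-transferase genes 3 rose and 0 fell, also when adjusted over the list alone, and 6 rose and 4 fell with the block. They were gst-21 (3.37), gst-5 (2.35, overlapping nos-1) and gsto-1 (1.30, overlapping kle-2). Camera gave an adjusted p of 0.763 for this list, whose median was -0.01 and mean 0.13.

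The endoplasmic reticulum unfolded protein response list had 6 of 21 members up and 0 down in wild type (11 up adjusted over the list alone, 13 with the block; camera adjusted p = 5.43e-21, and 0.0252 with an estimated correlation, 0.103 with both the block and an estimated correlation). Its rises were led by Y41C4A.11 (log2 3.31), the choline kinase gene ckb-2 (1.62 ± 0.20, from 316 ± 73.3 to 962 ± 93.9) and the chaperone gene dnj-7 (0.90). Of 18 immune effectors of the PMK-1 p38 pathway 5 rose and 1 fell (11 and 2 adjusted over the list alone, 11 and 3 with the block; camera adjusted p = 3.32e-09, and 0.255 with an estimated correlation). irg-5 (F35E12.5) rose from 151 ± 78.8 to 2037 ± 489 (3.87 ± 0.52) next to irg-6 and irg-4, and 3 members outside the naming rule, named after their values were seen, are lys-2 (0.95), clec-85 (0.86) and, lower, the saposin-like spp-1 (-0.92). In the DLK-1 p38 pathway list 1 of 10 rose, tbb-6 (2 adjusted over the list alone; 3 with the block, where dlk-1 and cebp-1 join it; camera adjusted p = 0.00013, and 0.112 with an estimated correlation). In the PMK-1 p38 pathway list 1 of 8 rose, the phosphatase gene vhp-1 (log2 0.48; 1 adjusted over the list alone; camera adjusted p = 0.0244, and 0.577 with an estimated correlation). 1 of 14 tubulin genes rose, tbb-6 again (2 adjusted over the list alone and 2 with the block, which adds tba-7 at 1.07, overlapping T28D6.3; camera adjusted p = 0.325, with a median of -0.01 and a mean of 0.26).

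C-type lectins moved both ways in wild type: 4 of 128 rose and 10 fell (11 and 18 adjusted over the list alone, 13 and 24 with the block; camera adjusted p = 0.0032 towards lower, and 0.741 with an estimated correlation). clec-209 rose from 2601 ± 374 to 13180 ± 1514 (log2 2.34), with values shared with F56A4.2, and the other rises were those of clec-206, clec-85 and clec-186 (0.69), the last named after its value was seen. Of 20 intestinal genes 1 rose, the protease gene cpr-3 (log2 1.13), and 1 fell, the protease gene cpr-4 (-0.78). Adjusted over the list alone 2 rose and 3 fell, and with the block 2 and 6, among them mtl-1, a metallothionein (2.28). Camera gave 0.0449 towards lower for them, and 0.741 with an estimated correlation, with a median of -0.13 and a mean of 0.01. Of 49 genes of fatty acid oxidation and lipases 1 rose, the peroxisomal thiolase gene daf-22 (log2 0.53; 1 adjusted over the list alone; camera adjusted p = 0.105), and with the block 1 rose and 7 fell, including lipl-3 (-2.41), lipl-1 (-1.48) and lipl-2 (-1.27). Of 111 neuronal genes 1 rose, nlp-29, an antimicrobial peptide gene of the epidermis (0.72; 0 adjusted over the list alone, 3 up and 3 down with the block; camera adjusted p = 0.14). Of 144 cuticle collagens 1 fell, col-135 (-0.79; 0 adjusted over the list alone; camera adjusted p = 4.57e-05 towards lower, and 0.869 with an estimated correlation). With the block 32 collagens fell, among them col-137 (-2.04) and col-156 (-2.13), in a list that also varied with the replicate number.

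The other 18 lists had 0 members past the threshold in wild type with limma without the block. Adjusted over the list alone 1 oxidative stress gene was lower, ctl-2, and 0 genes passed in the others. Together they hold 507 tested genes, of which 11 had an unadjusted p under 0.05, 0 passed with edgeR or limma-voom, 2 with DESeq2 and 26 with the block. Of 6 vitellogenin genes, which encode yolk proteins, 4 fell with the block, among them vit-3 (log2 -0.55, adjusted p = 0.00125), as did 11 of 81 cytosolic ribosomal protein genes, among them rps-25 (-0.20). Camera placed both lists lower without the block (adjusted p = 0.000147 and 2.58e-08), but not with an estimated correlation (0.555 and 0.843). The block also called 2 up and 3 down of 19 oxidative stress genes, with gst-10 (-0.71) and the catalase gene ctl-2 (-0.50, overlapping Y54G11A.7) among the falls. It called 1 up and 2 down of 24 genes of fatty acid desaturation, elongation and synthesis, with the desaturase gene fat-5 (0.69, overlapping twk-42) up. It called 1 up of 14 genes of the mitochondrial unfolded protein response, its regulator atfs-1 (ZC376.7, 0.25), and 1 up and 1 down of 52 moulting genes. The lists of the mevalonate and prenyl pathway (12 genes), small GTPases (33), cytosolic heat shock (17), phosphatidylcholine and one-carbon metabolism (13), oocyte and eggshell (20), sperm (88), germline mitosis and meiosis (23), muscle (20) and actin cytoskeleton (28) had 0 members past the threshold in either fit. So did the mitochondrially encoded genes (12), the nuclear encoded respiratory chain (35) and ribosomal RNA (11). Camera placed these last lists lower (adjusted p = 0.000495, 0.00475 and 0.0315), but not with an estimated correlation (0.583, 0.925 and 0.741).

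In the dlk-1 mutant fluvastatin was compared with control in the same way, to ask which genes respond in the mutant. Named genes of detoxification and of the infection response rose in the mutant too. cyp-35A3 went from 13.8 ± 9.62 to 1663 ± 336 normalised reads (SD, n = 3; log2 7.005 ± 0.40), cyp-35A5 changed by 6.10 ± 0.25, ugt-67 by 6.67 ± 0.39, irg-6 by 7.70 ± 0.63, clec-206 by 7.98 ± 0.68 and pgp-1 by 2.56 ± 0.24. pud-3 fell from 478 ± 256 to 16 ± 6.57 (-4.78 ± 0.66) and pud-4 from 113 ± 59.4 to 7.43 ± 4.26, and F49C12.7 (-2.18 ± 0.24, overlapping F49C12.6), cth-1 (-1.50 ± 0.28) and the lysozyme gene lys-4 (-1.50 ± 0.31) fell too. tbb-6 rose in the mutant from 38.9 ± 28.3 to 189 ± 7 (2.48 ± 0.48, adjusted p = 0.0316). hsp-4 went from 5973 ± 455 to 8099 ± 731 (0.44 ± 0.09), just short of the threshold without the block (adjusted p = 0.0518) and past it with the block (0.000322). irg-5 went from 861 ± 436 to 2947 ± 968 (1.88 ± 0.52) and passed only with the block (adjusted p = 0.194 without and 0.00326 with it). hmgr-1 stood at 802 ± 143 and 815 ± 97.8 (0.03 ± 0.18), hmgs-1 at 326 ± 67.4 and 315 ± 45 (-0.04), and hsp-6 (-0.04), hsp-60 (-0.12), fat-6 (-0.12), fat-7 (-0.99, adjusted p = 0.252), pmk-3 (0.22) and mkk-4 (0.15) did not pass in either fit. cebp-1 again passed only with the block (0.55, adjusted p = 0.0473).

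In the mutant limma called 175 genes up and 39 down, 143 and 28 of them by at least 2-fold. All 214 had groups that did not overlap, as did 647 of the 980 calls with the block. With the block 500 rose and 480 fell, and the share of rises went from 81.8% to 51.0%; the blocked count of 980 was 636 without mutant fluvastatin replicate 1. The count of 214 became 48 without all libraries of replicate 1 and 43 without those of replicate 3, and 137, 135 and 132 without mutant control replicate 3, mutant fluvastatin replicate 1 and mutant fluvastatin replicate 3; it was 362 with DESeq2 and 103 with only the groups compared in the fit.

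By list, 15 of 62 cytochrome P450 genes rose in the mutant and 0 fell (20 and 7 adjusted over the list alone, 23 and 9 with the block; camera adjusted p = 8.78e-10, and 0.0549 with an estimated correlation). Of the UDP-glucuronosyltransferases 22 rose and 2 fell (23 and 8 adjusted over the list alone, 26 and 8 with the block; 6.91e-15, and 0.243 with an estimated correlation); the falls were ugt-53 (-2.996) and ugt-30 (-1.73), the latter named after its value was seen. In the endoplasmic reticulum list 3 rose, ckb-2 (1.45), dnj-7 (0.68) and the disulfide isomerase gene pdi-6 (tag-320, 0.46), with 9 adjusted over the list alone, 11 with the block, and camera adjusted p of 6.83e-14, or 0.0883 with an estimated correlation. Of the PMK-1 effectors 3 rose, irg-6, irg-4 (2.97) and clec-85 (0.78, overlapping Y54G2A.40), with 7 up and 2 down adjusted over the list alone, 8 and 3 with the block, and camera adjusted p of 3.78e-05, or 0.472 with an estimated correlation. Of the ABC transporters 2 rose, pgp-1 and pgp-3 (2.001), with 7 up and 2 down adjusted over the list alone, 7 and 1 with the block, and camera adjusted p of 9.13e-05, or 0.32 with an estimated correlation. 4 glutathione S-transferase genes rose (4 adjusted over the list alone, 6 up and 5 down with the block; 0.487), with gst-21 (4.03) and gst-33 (1.97) the largest of those not overlapping another gene. 1 gene rose in each of the DLK-1 list and the tubulins (tbb-6), the PMK-1 pathway list (vhp-1, 0.51) and the fatty acid oxidation list (daf-22, 0.51). Adjusted over the list alone they had 2, 1, 1 and 1 up, with 2 down in the last, and with the block 3, 2, 1 and 2 up, with 3 down in the last. For the DLK-1 list camera gave 7.68e-05, or 0.0937 with an estimated correlation, and for the PMK-1 pathway list 0.0213, or 0.472 with an estimated correlation.

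The elongase gene elo-6 fell in the mutant (log2 -0.50 ± 0.08, adjusted p = 0.0111), the only 1 of 24 genes of fatty acid synthesis to pass (2 up and 4 down adjusted over the list alone and with the block; camera adjusted p = 0.023, and 0.472 with an estimated correlation). 3 lectin genes rose, clec-206, clec-209 (2.14) and clec-85, and 5 fell, from clec-70 (-2.48) to clec-150 (-0.74), named here after its value was seen (9 and 13 adjusted over the list alone, 11 and 22 with the block; camera adjusted p = 0.154 towards lower, with a median of -0.01 and a mean of 0.03). 1 collagen gene fell, col-135 (-0.81), with 0 adjusted over the list alone and 25 with the block (camera adjusted p = 0.00771, and 0.91 with an estimated correlation). The other 19 lists had 0 members past the threshold in the mutant without the block, and adjusted over the list alone 2 intestinal genes were up and 4 down, and 0 in the others. They hold 612 tested genes, of which 19 had an unadjusted p under 0.05, 0 passed with edgeR or limma-voom, 4 with DESeq2 and 45 with the block, among them 24 ribosomal protein genes and 4 vitellogenin genes, all lower. The other calls with the block included 8 of 20 intestinal genes (3 with DESeq2), 3 of 111 neuronal genes and 3 of 19 oxidative stress genes. Camera placed the ribosomal proteins (3.55e-12), heat shock genes (0.00461) and ribosomal RNA (3.86e-05) lower, and none of these held with an estimated correlation (0.581, 0.472 and 0.406). The mevalonate list again had 0 members past the threshold in either fit (camera adjusted p = 0.702).

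**Figure D2:**
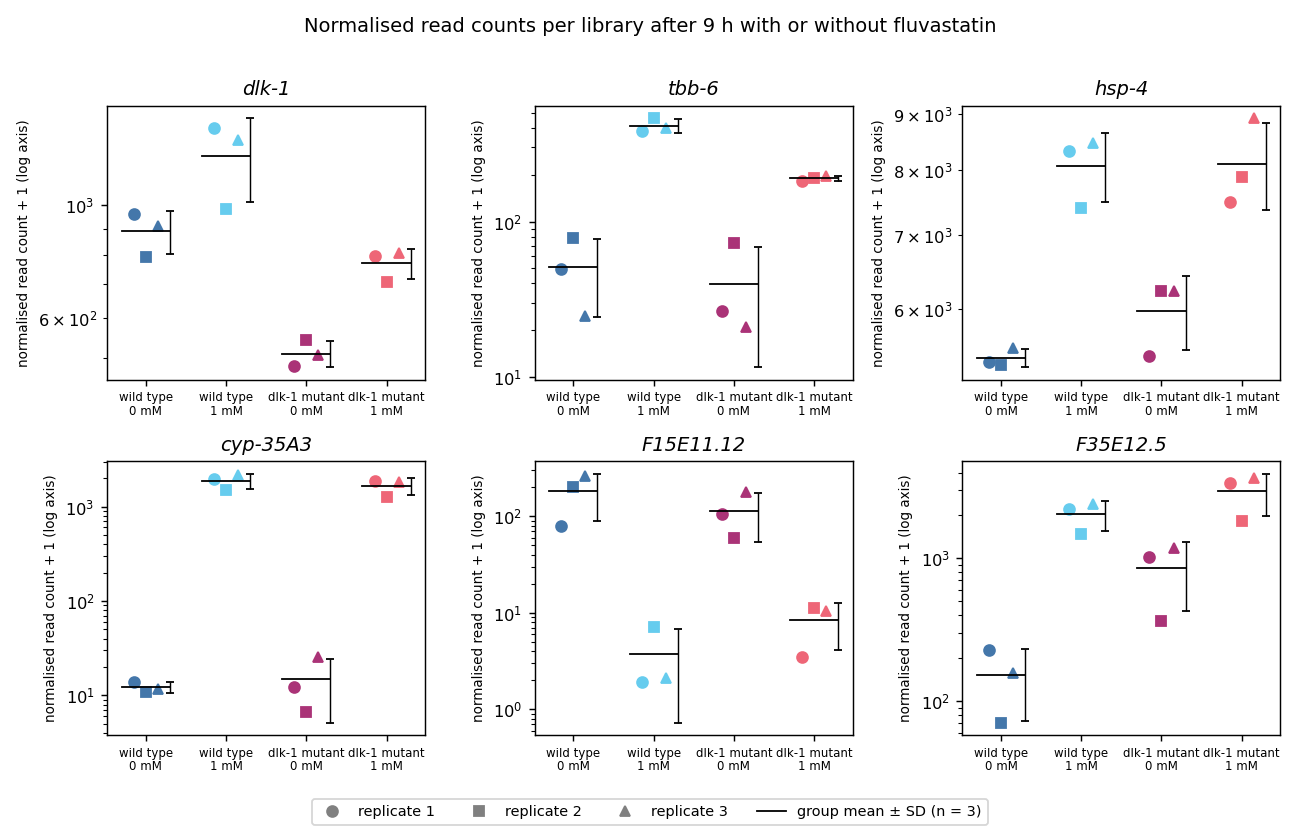
Normalised read counts + 1 on a log axis for dlk-1, tbb-6, hsp-4, cyp-35A3, pud-4 (F15E11.12) and irg-5 (F35E12.5) in each of the 12 libraries, with bars for group mean and SD (n = 3). cyp-35A3 goes from 11.2 to 1869 in wild type and from 13.8 to 1663 in the mutant, while dlk-1 without fluvastatin stands at 888 in wild type and 509 in the mutant.

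**Figure D3:**
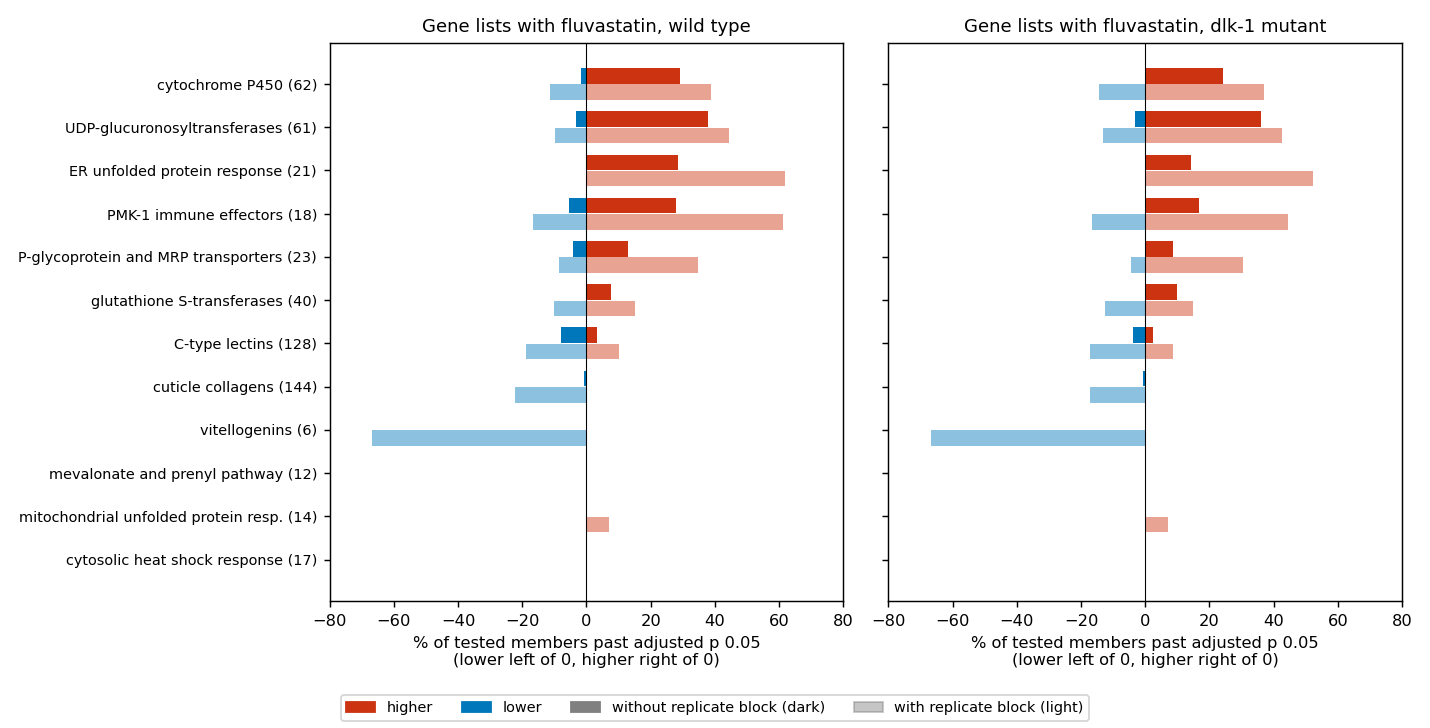
Percent of the tested genes of each of 12 lists past an adjusted p of 0.05, up to the right and down to the left, for fluvastatin in each genotype without (dark) and with (light) the replicate block. Of 62 cytochrome P450 genes 18 rose in wild type and 15 in the mutant, and 32 and 25 collagens fell with the block.

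The overlap of both effects addresses which responses wild type and mutant share. How far the mutation lowers DLK-1 activity was not measured. Among the shared rises were cyp-35A3, ugt-67, irg-6, pgp-1, tbb-6, ckb-2 and vhp-1, and among the shared falls pud-3, pud-4, thn-2, cth-1 and col-135. 169 genes rose in both genotypes, against 2.43 for independent lists of these sizes, and 36 fell in both, against 0.166; 0 were called in opposite directions. All 282 genes called in wild type had the same sign in the mutant, and all 214 called in the mutant had the same sign in wild type. Across all 15529 genes the log2 changes of both genotypes correlated with a Pearson r of 0.788 and a Spearman rho of 0.514. Across the 291 genes called in either the values were 0.984 and 0.982, but these genes were picked by their effects in the same fit, which raises the correlation. Genes are not independent replicates. The general response of 205 genes became 770 with the block (422 up and 348 down), 45 without all libraries of replicate 1, 40 without those of replicate 3, and 134, 134 and 129 without mutant control replicate 3, mutant fluvastatin replicate 1 and mutant fluvastatin replicate 3. It was 320 with DESeq2 and 95 with only the groups compared in the fit.

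**Figure D4:**
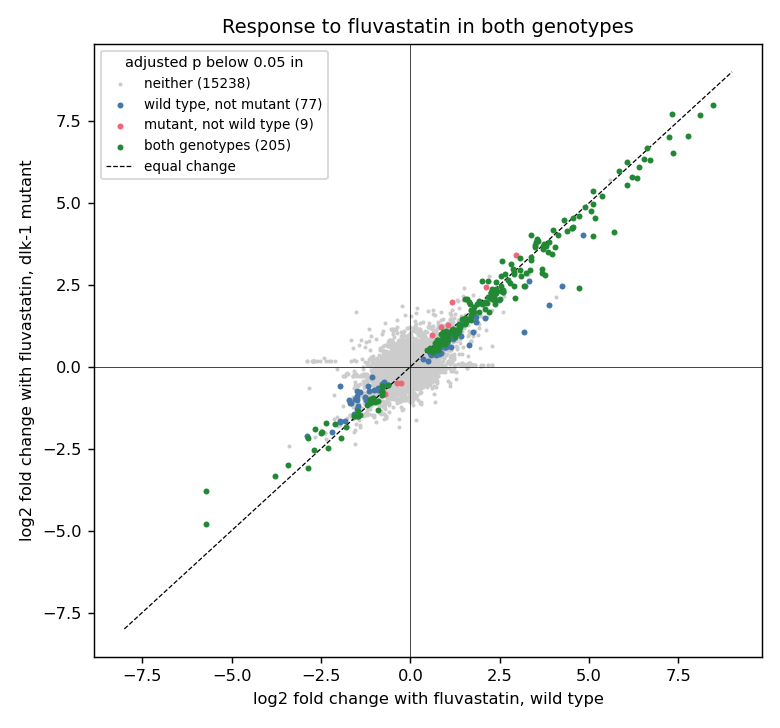
Log2 change with fluvastatin in wild type (horizontal) against the dlk-1 mutant (vertical) for 15529 genes, coloured by where a gene passed. 205 genes passed in both, 77 in wild type and not the mutant, and 9 in the mutant and not wild type, which is no test of the difference between them.

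The difference between these effects asks which responses differ in the mutant, and through it bears on the p38 cascade only as far as the mutation lowers it. The lowest p-values belonged to ugt-19, whose mean went from 172 ± 16.6 to 253 ± 22.7 in wild type and from 117 ± 20.1 to 90.6 ± 15.9 in the mutant (difference of log2 changes -0.93 ± 0.26, SE, n = 3 per group), and F09C8.1 (0.76). irg-5 had a log2 change of 3.87 in wild type and 1.88 in the mutant, a difference of -1.99 ± 0.73, and started higher in the mutant. The cullin gene cul-6 (-0.70), the serpin gene srp-7 (-0.41) and pud-4 (1.92) were also among the 20 lowest p-values. For tbb-6 the difference was -0.70 ± 0.67 and for hsp-4 -0.13 ± 0.13. All of these had an adjusted p of 1.0 in both fits. With limma 0 genes passed for the difference, with or without the block, where 29 and 386 had an unadjusted p under 0.05. edgeR and limma-voom gave 0 and DESeq2 gave 0, while DESeq2 with the block gave 1, irg-5 (log2 -1.997 ± 0.36, adjusted p = 0.000457). The p38 dependent response, which needs this test, therefore held 0 genes with limma in both fits and 1 with DESeq2 and the block. In the simulated data 6% of 2-fold differences were recovered without the block and 80% with it. Those data held many changed genes, which makes the adjusted threshold easier to pass. The shares therefore cannot be carried over to this comparison, where limma called 0 genes. irg-5 (-1.99) and pud-4 (1.92) did not pass with the block, although 88% of simulated 4-fold differences did. Small differences may thus be missed in either fit.

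With limma no member of any list passed for the difference, over all genes or adjusted over the list alone without the block. The lists held 1204 genes, of which 4 had an unadjusted p under 0.05. DESeq2 with the block called 1 of them, irg-5, a PMK-1 effector. With the preset correlation, lists that camera placed lower in the mutant's response than in the wild type's were, first, the PMK-1 effectors (median -0.36, adjusted p = 2.45e-05), the endoplasmic reticulum list (median -0.11, 6.39e-06) and the heat shock list (median -0.19, 6.39e-06). With an estimated correlation these did not hold (adjusted p = 0.759, 0.615 and 0.615). The cytochrome P450 list was placed lower (median -0.10, 0.00947) and the mitochondrially encoded genes higher (median 0.17, 4.79e-05), and neither held with an estimated correlation (0.615 and 0.759), nor did any other list, with 0.615 as the lowest adjusted p.

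The comparison of genotypes without fluvastatin asks what the mutation changes at baseline. With the replicate block irg-5 was higher in the mutant (861 ± 436 against 151 ± 78.8, log2 2.49, adjusted p = 0.0252), as were the immune effector gene C17H12.8 (0.62, 0.026) and the ribosomal protein gene rpl-30 (0.41, 0.011). Lower were fat-5 (184 ± 30.9 against 339 ± 60.5, -0.88, with an SE of 0.23 without the block and an adjusted p of 0.00526 with it), lfe-2, which encodes an inositol trisphosphate kinase (-0.79, 0.00589), sptl-2, which encodes a subunit of serine palmitoyltransferase (-0.47, 0.0322), and dlk-1 itself. Of 18 PMK-1 effectors 2 were higher with the block, and 10 when adjusted over the list alone (2 without the block). Camera gave 2.76e-09 for them without the block, but 0.763 with an estimated correlation, and 0.0686 with both the block and an estimated correlation. The calls of limma rest on the block: without it limma called 0 genes, with 125 at an unadjusted p under 0.05, and edgeR and limma-voom gave 0. DESeq2 gave 4, dlk-1, irg-5, F56G4.6 and T28A11.2. The block called 8 up and 7 down, each in 3 of 3 pairs, a count of 15 that became 7, 0 and 5 without wild-type control replicate 1, 2 and 3, and 4 and 5 without mutant control replicate 2 and 3. Without the block, leaving out all libraries of replicate 2 gave 1 gene, irg-5.

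The comparison of genotypes with fluvastatin asks the same under the drug. With the replicate block ugt-19 was lower in the mutant (90.6 ± 15.9 against 253 ± 22.7, log2 -1.48, adjusted p = 0.000477). The fit without the block gave this change an SE of 0.18 and an adjusted p of 0.12. The desaturase gene fat-5 (-0.77, 0.0149), elo-6 (-0.39, 0.0218), spl-2 (tag-38), which encodes a sphingosine phosphate lyase (-1.12, 0.0323), and ZK550.2 (-0.86, 0.0205) were lower too, and the sugar transporter genes swt-3 (C06G8.1, 0.72, 0.0218) and swt-1 (K02D7.5, 0.55) and rpl-30 (0.42, 0.0149) were higher. tbb-6 stood at 189 ± 7 in the mutant against 414 ± 41.2 (-1.12, with an SE of 0.48 without the block and an adjusted p of 0.442 with it). Of 62 cytochrome P450 genes 1 was lower with the block (3 adjusted over the list alone; camera adjusted p = 3.44e-06, and 0.155 with an estimated correlation). Of 61 UDP-glucuronosyltransferase genes 1 was higher, ugt-30 (1.00), and 2 were lower, ugt-19 and ugt-62 (-0.63), with 1 and 6 adjusted over the list alone (3.22e-05, and 0.551 with an estimated correlation). Of 24 fatty acid synthesis genes 2 were lower, fat-5 and elo-6 (4 adjusted over the list alone; 0.00425, and 0.551 with an estimated correlation). Ribosomal RNA (11 genes), a mark of RNA selection, was lower too, in 3 of 3 pairs (0 past the threshold, 3 adjusted over the list alone; 9.39e-06, and 0.551 with an estimated correlation). Whether RNA selection shifts the other lists was not tested. Without the block limma called 0 genes, with 227 at an unadjusted p under 0.05, and edgeR and limma-voom gave 0, while DESeq2 gave 7. The block called 15 up and 27 down, each in 3 of 3 pairs. On simulated data 12 false calls arose in this comparison with the block, beside genes truly changed there, so they give no false share for these calls. The count of 42 was 25 and 18 without wild-type control replicate 1 and 2, and 4, 3 and 2 without wild-type fluvastatin replicate 1, 2 and 3. It was 72 with DESeq2, 9 with summed transcript models, 10 for changes of at least 2-fold and 1 at an adjusted p under 0.01. It was 69 without mutant control replicate 1, and 3, 1 and 1 without mutant fluvastatin replicate 1, 2 and 3. Without the block, leaving out mutant control replicate 1 gave 1 gene, C33G8.2 (1.56, adjusted p = 0.0215), named after its value was seen.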

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

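The difference between the genotypes' responses was tested as planned, and of the tests in this part only DESeq2 with the replicate block was chosen after the result was seen. Among the 20 lowest p-values of that difference, 7 genes changed one way in all 3 pairs of wild type and the other way in all 3 pairs of the mutant. The test of the difference itself passed for none of the 7 with limma, with or without the block (adjusted p = 1.0), and they were picked out of 15529 genes. ugt-19, a UDP-glucuronosyltransferase gene, went from 172 ± 16.6 to 253 ± 22.7 normalised reads in wild type and from 117 ± 20.1 to 90.6 ± 15.9 in the mutant (SD, n = 3; difference of log2 changes -0.93 ± 0.26, SE). gnrr-4, which encodes a receptor related to that for gonadotropin-releasing hormone, went from 71.7 ± 12.9 to 51.9 ± 9.82 and from 45.1 ± 2.43 to 62.8 ± 3.2 (0.93 ± 0.31). ctn-1, an alpha-catulin gene, went from 760.2 to 685 and from 739 to 868 (0.39). skr-4, a gene of the ubiquitin ligase complex, went from 139 to 176 and from 147 to 124 (-0.58). dgat-2 (F59A1.10, overlapping F59A1.11), which encodes an acyltransferase of triglyceride synthesis, went from 232 to 265 and from 213 to 188.5 (-0.36). abf-6, an antibacterial factor gene, went from 64.1 to 51 and from 46.6 to 58.8 (0.65). ttc-1 (C34B2.5) went from 667 to 725 and from 727 to 649 (-0.28). DESeq2 with the block called a different gene for the difference, irg-5 (log2 -1.997, adjusted p = 0.000457), which rose in wild type and, with the block, in the mutant.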

How the results depend on the processing

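Chosen after the data were seen were summed transcript models, TMM scaling, leaving out a whole replicate number, every setting that adds a second change to the block, and the genotype effect averaged over treatments. The design had planned edgeR with TMM factors as the main test for raw counts. limma took its place because the values are normalised, and edgeR with TMM factors on the recovered reads was then added as an alternative. No named gene that was called turned its direction in any alternative. The balance of calls did turn for the genotypes without fluvastatin with the block, from 8 up and 7 down to 7 and 9 with library size scaling, 2 and 3 without replicate 3 of either control group, 0 and 1 without all of replicate 3, and 1 and 2 at an adjusted p under 0.01. It also turned for the averaged genotype effect, from 56 up and 106 down to 46 and 36 without mutant fluvastatin replicate 3. Of the named genes' alternatives 4834 kept their side of the threshold, 389 lost the call and 65 gained it. Only called genes, 42 in wild type and 39 in the mutant, can lose a call, and the 4834 include genes never called, so 389 is no share of that whole. The cause of the moves was not tested. For fluvastatin in wild type (282 genes) the count was 1091 with the replicate block, 166 with only the groups compared, 437 with DESeq2, 169 at an adjusted p under 0.01, and 56 and 43 without replicates 1 and 3, with 167 to 278 when 1 library was left out and 257 without replicate 2. In the mutant (214) it was 980, 103, 362, 133, 48 and 43 in the same order, with 132 to 205 when 1 library was left out and 217 without replicate 2. The general response (205) held 770, 95, 320, 128, 45 and 40 genes, with 129 to 188 and, without replicate 2, 198. The genotypes differed without fluvastatin in 0 genes, 15 with the block, 4 with DESeq2 and 1 without replicate 2, and with fluvastatin in 0, 42 with the block, 7 with DESeq2 and 1 without mutant control replicate 1. Among counts with the block, an adjusted p under 0.01 left 684 of 1091 in wild type, 572 of 980 in the mutant, 496 of 770 in the general response, and 3 of 15 and 1 of 42 between genotypes without and with fluvastatin. Changes of at least 2-fold numbered 407, 321, 276, 2 and 10. Leaving out 1 library gave 720 to 1218, 636 to 1001, 557 to 702, 0 to 22 and 1 to 69. Without replicates 1, 2 and 3 the blocked mutant count was 561, 613 and 558 and the blocked count between genotypes with fluvastatin 13, 2 and 3. Without replicate 3 the blocked wild-type count was 593, and the blocked general response was 483 and 404 without replicates 1 and 3. Between genotypes without fluvastatin the blocked count was 2 and 1 without replicates 2 and 3. DESeq2 with the block gave 25 and 72 between genotypes, and 1 for the difference of responses and the p38 dependent response in place of 0; summed transcript models gave 9 in place of 42. The averaged genotype effect (162) was 220 with library size scaling, 0 without the block, with 363 genes at an unadjusted p under 0.05, and 63 to 247 with 1 library left out, most without mutant control replicate 1. Of 42 genes named and called in wild type, 30 lost the call without replicate 1, 32 without replicate 3, 9 without replicate 2, 12 with only the groups compared, 8 with limma-voom, and 0 with DESeq2 or the block. A left-out library leaves 2 in its group and leaving out a replicate number takes 4 libraries, but fewer samples alone do not set these counts: without the block, leaving out replicate 2 changed the fluvastatin counts little, and with the block, leaving out mutant control replicate 1 raised the count in wild type and those between genotypes. Depth limits low genes: at 9370975 to 12438131 reads, changes of genes under 10 normalised reads in control rest on few reads.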

Other observations

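The genotype effect averaged over both treatments, its swaps, the symbol families and the test of stage lists were chosen after the results were seen. The averaged fit takes the control and fluvastatin libraries of 1 genotype and replicate number as separate samples. The labels do not say whether these came from 1 culture. If they did, the same units are counted more than once, and the counts and the 6 pairs below overstate the evidence. Averaged over treatments in the fit with the replicate block, 56 genes were higher and 106 lower in the dlk-1 mutant (limma adjusted p under 0.05), and 12 of the 106 are copies of the 5S ribosomal RNA gene with identical values (log2 -1.03, adjusted p = 0.043), so that 1 measurement near the threshold is counted 12 times; with library size scaling 56 were higher and 164 lower. Of 18 immune effectors of the PMK-1 p38 pathway 5 were higher and 0 lower: sysm-1 (T24B8.5, log2 1.08), irg-5 (1.497), dod-22 (0.64), dod-24 (0.80) and C17H12.8 (0.44), and adjusted over the list alone 8 were higher and 1 lower. Camera gave an adjusted p of 1.98e-05 for the list, and 0.17 with an estimated correlation. Lower in 6 of 6 pairs, as nearly all called genes were in their direction, were ugt-19 (-1.02, adjusted p = 0.00026), fat-5 (-0.82, 0.00026), lfe-2 (-0.71, 0.00026), dlk-1 (-0.74, 0.000525) and gst-38 (-0.92, 0.0136). The largest effect was that of trf-2 (Y110A7A.2), higher in the mutant (log2 4.73, limma adjusted p = 0.0419). It stood at 21.4 ± 26.8 in wild type and 269 ± 44.3 in the mutant without fluvastatin, and at 17 ± 26.7 and 238 ± 33 with it. The wild-type SD was larger than the mean at both doses, so the log2 size rests in part on low wild-type values. Without the block 0 genes passed with limma, with 363 at an unadjusted p under 0.05. Leaving out any 1 of the 12 libraries moved the blocked count of 162, from 63 without wild-type fluvastatin replicate 3 to 247 without mutant control replicate 1, and gave 46 higher and 36 lower without mutant fluvastatin replicate 3.

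Among symbol families, the nspc genes, short secreted peptides of closely similar sequence whose reads cannot always be parted, fell with the block in 20 of 20 members in wild type and 17 of 20 in the mutant (Fisher's exact test, adjusted p = 1.22e-28 in wild type). The test counts as separate genes that may share reads, so this p-value is too low. Without the block the nspc family did not pass in either genotype. Nuclear hormone receptor genes rose with the block in 26 of 181 members in each genotype, and without it in 10 in wild type (adjusted p = 0.00626). Without the block this family did not pass in the mutant. Saposin-like spp genes fell in 5 of 16 members in wild type without the block (adjusted p = 2.53e-07) and in 2 in the mutant (0.0364). With the block 8 of 16 fell in each genotype (Fisher's exact test, adjusted p = 3.06e-07 in wild type and 1.64e-07 in the mutant).

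Other groupings of the same libraries were counted for each comparison. For fluvastatin in wild type and in the mutant, 1 of 10 splits gave as many genes, the real 1 (282 and 214, against a highest other of 0). With the block each comparison of 2 groups has 4 splits that part the same pairs, of which 1 gave as many, the real 1: for fluvastatin 1091 and 980 against a highest other of 0, and for the genotypes 15 against 8 without fluvastatin and 42 against 0 with it. With 10 or 4 splits no share under 0.05 can be had. For the general response the real split gave 205 genes against a highest other of 0 in 100 splits, and 770 against 0 in 32 with the block. A gene counts here only if called in both genotypes, and every other split of either effect gave 0. These splits therefore repeat those of the single effects. They argue against chance in both genotypes at once, and do not test either genotype alone. Where the real count is 0, every split gives as many, so the counts of splits say nothing about chance. This holds for the genotypes without the block (10 of 10 splits, highest other 0) and for the difference and the p38 dependent response (100 of 100 splits, highest others 2300 and 94, and 32 of 32 with the block, highest others 162 and 107). The split with 162 exchanges the genotypes of all fluvastatin libraries, which is the averaged genotype effect, and both that and 2300 point to a structure of the samples. Since the averaged effect is the highest of those 32 arrangements, its rank among them (1 of 32, 162 against 17) is not a test, and chance was not tested for it.

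Replicate 2 of all groups stood apart on the first component. Sequencing depth is argued against: thinning all libraries to 9370975 reads left 57.8% of the variance on that component. The replicate 2 libraries, at 10453386 to 11993994 reads, also lay inside the range of the others. Leaving out the 100 genes of highest mean left 58.5%. This cannot decide whether a few abundant genes matter, since 100 genes weigh little among all tested genes on log2 values. A candidate explanation is that animals of replicate 2 were at another developmental stage. All 3 stage lists (collagen, moulting and sperm) ranged more over replicate numbers than 95% of random lists, with list medians in replicates 1, 2 and 3 at 0.94, -0.59 and -0.14 for moulting genes and 0.42, -1.04 and 0.63 for sperm genes. Muscle and neuron lists did so too, and so did the oocyte and vitellogenin lists, but with replicate 1 lowest (-0.24 and -0.32) and replicate 2 not apart from replicate 3 (0.13 and 0.11 against 0.10 and 0.23), so that a stage difference of replicate 2 alone does not account for all lists and other differences in culture stay open. The comparison with random lists cannot decide between these. Its random lists held genes drawn singly, so a list whose genes move together ranges more whatever the cause.

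Collagen and nspc genes were lower with fluvastatin in the fit with the block. Scaling between libraries as the whole cause is argued against, since library size scaling kept 100% of the 52 calls in wild type and 88.1% of the 42 in the mutant. A shift of the animals along the axis that separates the replicates is argued against as the whole cause: across all tested genes the blocked effect in wild type correlated with replicate 2 minus the others at a Pearson r of 0.056, and over the 144 collagens alone at 0.048 (Spearman rho -0.135), where the explanation needed at least 0.3. The bound of 0.1 set beforehand for excluding it holds less firmly, as r was 0.101 in wild type and 0.127 in the mutant without genes changed 2-fold. It stays open as a part of the cause, since Spearman's rho over all genes was 0.214 and 49 of the 52 called genes were also lower in replicate 2, as the collagen list was as a whole; genes are not independent replicates, and a direct effect of fluvastatin on these genes was not tested.

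The response was slightly smaller in the mutant over 899 genes whose response averaged over both genotypes passed with the block and was at least 0.5 log2 units, with a median difference in size of -0.093 log2 units. The effect of the pseudocount on low values is argued against, as the median was -0.097 over 313 genes with a mean of at least 200 and a pseudocount of 0.1. Sequencing depth is argued against by a median of -0.101 after thinning to equal reads. Chance cannot be excluded: 2 of 32 swaps of the genotype lay as far from 0, with a highest other of 0.097 in size. A small dependence on DLK-1 stays open as a hypothesis.

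2 further hypotheses were tested. As cul-6 and skr-4 belong to the intracellular pathogen response, this group may respond differently in the mutant: its median difference lay at percentile 9.21 of random lists, inside the bounds set beforehand for excluding it, but with 5 genes in the test this excludes little and the question stays open. Genes that differ between genotypes with the block might be linked to dlk-1 on chromosome I. Of 49 such genes 4 lie there (8.2%), against 2512 of 15285 tested genes (Fisher's exact test, two-sided p = 0.173). An excess of these genes on chromosome I was therefore not seen. The 45 on other chromosomes cannot be linked to dlk-1 by position, so the test says nothing about their source. Differences between the strains on other chromosomes were not tested.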
